A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

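RNA was measured in 8 libraries of Saccharomyces cerevisiae, in 4 groups of 2 that the labels describe as biological replicates. The library used as 30 min replicate 2 is numbered 3 in its title and 2 in its description, and the description was followed. The Nab2 anchor-away strain was sampled before rapamycin (0 min) and after 15 and 30 min with rapamycin at 1 µg/ml, and a control strain without the FRB tag was sampled after 30 min with the same dose. Per the labels, ribosomal RNA was depleted from total RNA, most small RNAs were removed in a clean-up step, and strand-specific libraries were made with random primers and dUTP.

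The values are whole-number read counts per annotated feature, as the authors deposited them, with no normalisation. The submitters' processing notes name GSNAP 2012-01-11, HTSeq 0.5.3, bedtools 2.17.0 and genome build R64. The role of each tool, the counting rule and any removal of duplicate reads are not given in the sources used here. Fission yeast RNA was added as a spike-in per the labels, and the count table used here held 0 spike-in features. The library scaling therefore followed the alternative written for that case, edgeR's TMM factors over all tested features. Every fold change is thus relative to the bulk of the RNA in each library, and a change in total RNA output per cell cannot be read from it.

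The table held 7711 features. Removing 29 exact repeats and 23 further entries that shadowed a gene left 7659, of which 5425 were transcripts of open reading frames (ORF transcripts), 925 cryptic unstable transcripts (CUTs), 847 stable unannotated transcripts (SUTs) and 350 introns. Gene names were joined to a reference table, which matched 5779 of 6074 names. Another 297 features were composites that carry more than 1 gene name, written with a slash (RPL7B/SNR59), and their counts cannot be assigned to one of the genes. Reads shared between paralogs may have been dropped or assigned by a rule not given in the sources used here, so values of single members of paralog pairs, ribosomal protein genes above all, are uncertain to that extent.

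Totals over the features used ranged from 4832948 to 17023017 counts per library. Ratios of counts divide the observed counts, summed over each group, by that group's TMM-scaled library total. Their 95% intervals come from the exact binomial (Clopper-Pearson) method, scaled in the same way. These intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

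Counts were tested in R 4.3.3 with edgeR 4.0.16. Features were kept by filterByExpr with its default settings, which left 6191. A single model with 1 term per group was fitted to all 8 libraries (glmQLFit with robust = TRUE), leaving 4 residual degrees of freedom, a common dispersion of 0.373 and a median prior of 13.59 degrees of freedom. The biological coefficient of variation was 0.611. Differences between groups were tested 2-sided with edgeR's quasi-likelihood test, and a feature passed at a Benjamini-Hochberg adjusted p under 0.05. An exact permutation test of 2 libraries against 2 cannot go below p = 0.33, so single features were tested only with the model that shares information across genes. The 5 comparisons share libraries: a feature whose 0 min libraries were low by chance appears raised at both later times. This overlap was compared with 40 simulated draws in which nothing changed.

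Gene lists were tested with camera in limma 3.58.1 with an inter-gene correlation preset to 0.01, with camera with an estimated correlation, and with fry, each adjusted over 31 lists per comparison. Counts of members that passed are given over all genes tested and adjusted over the list alone. Members are features, so a gene with more than 1 feature, such as GAT1 (features ST0992 and ST0993), counts more than once. The gene lists, the tests, the comparisons, the rule for named genes and the alternatives of the last paragraph, except those named there as later, were fixed before the data were examined. The feature classes named in the table (CUT, SUT, intron, snRNA) and the split of ribosomal protein genes by the presence of an intron feature were added afterwards. No Ty element was found in the table.

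Named genes follow 3 parts of a rule. NAB2, RPL13A, FPR1 and TOR1 are named as components of the anchor system. In each comparison the 8 largest rises and 8 largest falls are named among features that passed the test, had a mean of at least 50 counts and had both libraries of one group above both of the other. In each list the 2 members with the smallest p, the member with the highest mean count and the largest passing change against the direction of the majority are named. OLE1 falls outside the rule and was chosen after its values were seen.

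The share of each library's counts in each feature class was compared between the 4 anchor-away libraries after rapamycin and the other 4 with a 2-sided exact permutation test over 70 splits. That grouping was chosen after the data were seen.

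The procedure was tested on a single simulated draw per comparison, with library sizes and edgeR's fitted dispersions taken from the table. Changes were placed only in features with a mean of at least 50 counts, so recovery of features with fewer counts was not measured. The draws did not model libraries with many features at 0, so false calls in the real table may differ. For 15 over 0 min, edgeR recovered 16.4% of simulated changes of 1 log2 unit, 56.7% of changes of 2 and 72.7% of changes of 3, with 5 false calls among 102. For 30 over 0 min the shares were 16.4%, 49.3% and 72.7%, with 4 false calls among 97. For 30 min over the control they were 11.9%, 50.7% and 71.2%, with 7 false calls among 96. DESeq2 1.42.0 on the same simulated tables made 41 false calls among 152, 30 among 134 and 45 among 148.

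Alternatives were DESeq2 size factors, total library size, upper-quartile scaling, scaling on mitochondrial genome features, scaling on snoRNA features, the DESeq2 Wald test, limma-voom, no filter on low counts, a group mean of at least 50 counts, a replicate block, each library left out in turn, and a fit to only the 4 libraries compared. After the data were seen, limma-voom with library quality weights, a fit without the 3 libraries in which over 20% of features had 0 counts (leaving 1 library in each group after rapamycin, assumed to vary like the others), and a crossed replicate block were added.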

Results

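Nab2 is a nuclear protein of budding yeast that binds poly(A) tails. In the anchor-away strain it carries an FRB tag, and the ribosomal protein Rpl13a carries the matching FKBP12 tag, so that rapamycin ties Nab2 to ribosomal protein leaving the nucleus. The strain carries the tor1-1 allele and a deletion of FPR1, which together make cells resistant to rapamycin itself. RNA was counted in 2 biological replicates of this strain at 0, 15 and 30 min of rapamycin, and in 2 of a control strain without the FRB tag at 30 min. Total counts were 17023017 and 14711873 at 0 min, 9308525 and 7562689 at 15 min, 9207040 and 4832948 at 30 min, and 8883059 and 10435091 in the control. Levels of single features are given as CPM, counts relative to the TMM-scaled library total. In 3 libraries over 20% of features had 0 counts: 24.4% in 15 min replicate 1, 28.2% in 30 min replicate 2 and 28.2% in control replicate 1, against 9.18% to 15.4% in the other 5. Each group after rapamycin holds 1 of these libraries of low complexity and the 0 min group holds none, so every comparison below includes at least 1.

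The components of the anchor system were measured first. NAB2 (feature ST4817, chromosome VII, 278946 to 280523, build R64) had 238 ± 37.0 CPM at 0 min, 169 ± 6.77 at 15 min, 215 ± 17.4 at 30 min and 152 ± 45.0 in the control (mean ± SD, n = 2). Its log2 fold change was -0.49 ± 0.28 (SE) at 15 min (adjusted p = 0.851 in edgeR's quasi-likelihood test) and -0.14 ± 0.27 at 30 min (edgeR adjusted p = 0.926), and against the control it was 0.50 ± 0.28 (edgeR adjusted p = 0.312). RPL13A, the anchor, had 328 ± 75.2, 264 ± 20.1, 178 ± 86.4 and 415 ± 42.6 CPM in the same order, and was lower at 30 min than in the control, with a log2 fold change of -1.23 ± 0.31 (edgeR adjusted p = 0.0234). RPL13A has a paralog, so its level is uncertain where reads match both. TOR1 had means of 103, 91.6, 140 and 99.3 CPM and passed no test. FPR1, which is deleted in the anchor-away strain per the labels, had raw counts of 3 and 31 at 0 min, 0 and 1 at 15 min, 29 and 0 at 30 min, and 0 and 4 in the control.

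Cryptic unstable transcripts (CUTs) are short nuclear RNAs that the exosome normally degrades. Their share of the counts was 0.0583% ± 0.00184 at 0 min, 0.122% ± 0.00453 at 15 min, 0.182% ± 0.022 at 30 min and 0.0499% ± 0.0107 in the control (mean ± SD, n = 2). The mean over the 4 anchor-away libraries after rapamycin was 2.81 times that over the other 4 libraries. The matching ratios were 1.78 for snRNAs, the RNAs of the spliceosome, 1.64 for snoRNAs, which guide the modification of ribosomal RNA, and 1.52 for stable unannotated transcripts (SUTs). Transcripts of open reading frames took 94.2% of counts at 0 min, 91.8% at 15 min, 90.3% at 30 min and 93.7% in the control, a ratio of 0.97. In each of these 5 classes all 4 libraries lay on one side of the other 4. The 2-sided exact permutation p was 0.0286, the smallest that 70 splits can give, and 0.0572 after Benjamini-Hochberg adjustment over 10 classes, which does not pass 0.05. The share of tRNA features had a ratio of 2.67 (exact p = 0.0857), that of mitochondrial genome features 1.48 (exact p = 0.1143) and that of introns 0.89 (exact p = 0.2857). Without the 3 libraries of low complexity the ratios were 2.73 for CUTs, 1.74 for snRNAs, 1.7 for snoRNAs and 1.6 for SUTs, where the smallest possible exact p is 0.1. These shares and ratios are relative to all counts, so a rise in 1 class and a loss of the rest give the same share.

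**Figure D1:**
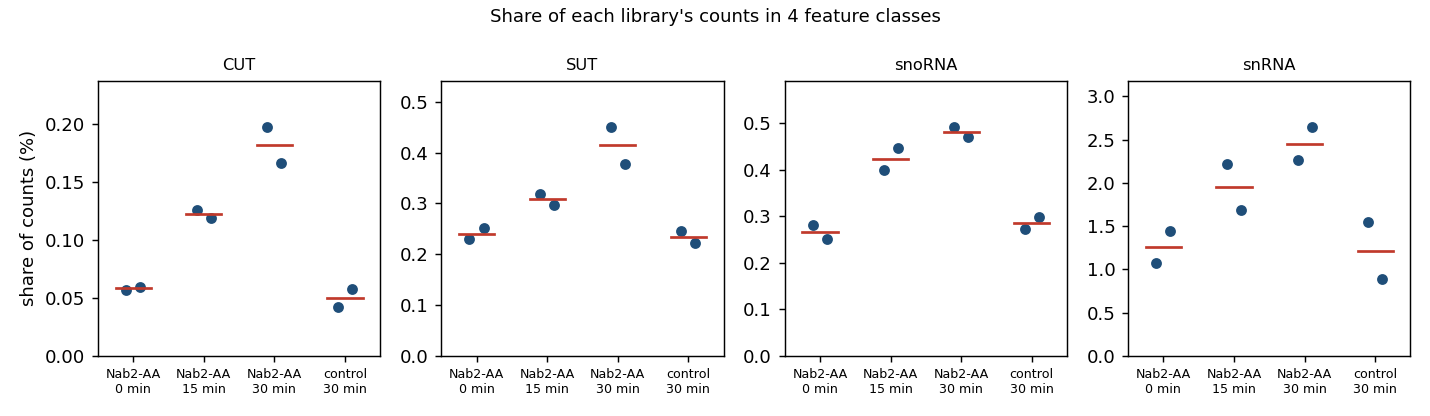
Share of each library's counts, in percent, in CUTs, SUTs, snoRNAs and snRNAs, by group; points are the 2 libraries of each group and red lines their mean. The mean CUT share is 0.0583% at 0 min, 0.122% at 15 min, 0.182% at 30 min and 0.0499% in the control.

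The scaling sets the level against which changes are read. The median log2 fold change of all tested features was -0.06 for 15 over 0 min, -0.05 for 30 over 0 min, 0.06 for 30 min over the control, -0.04 for 30 over 15 min and -0.08 for the control over 0 min. In the same order it was -0.24, 0.14, 0.43, 0.33 and -0.25 by total library size, -0.53, -0.49, -0.25, 0.03 and -0.19 on mitochondrial genome features, and -0.90, -0.70, -0.22, 0.14 and -0.42 on snoRNA features. Upper-quartile scaling moved it to 0.22 for 30 min over the control. The median of the CUTs stayed above 0 for 15 over 0 min, 30 over 0 min and 30 min over the control under every scaling tried, at its lowest 0.33, 0.32 and 1.05 on snoRNA features.

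The comparison of 15 min with 0 min addresses the early change after Nab2 is anchored away. No control was sampled at 15 min, so anchoring cannot be told apart from rapamycin exposure or time here. NRD1, HRP1 and TRF5 rose. NRD1 (feature ST6456, chromosome XIV, 172588 to 174315), which encodes an RNA-binding protein that ends transcription of short noncoding RNAs, went from 125 ± 24.5 to 338 ± 4.14 CPM (mean ± SD, n = 2), a log2 fold change of 1.44 ± 0.26 (SE). HRP1 (feature ST2998, chromosome XV, 87844 to 89448), which encodes a subunit of an mRNA cleavage factor, went from 413 ± 4.14 to 1075 ± 98.1, a log2 fold change of 1.38 ± 0.24. TRF5 (feature ST2722, chromosome XIV, 66517 to 68445), which encodes a poly(A) polymerase of the nuclear surveillance complex TRAMP, rose by 1.91 ± 0.36 on the log2 scale. The edgeR adjusted p-values were 0.0275 for NRD1, 0.0250 for HRP1 and 0.0339 for TRF5. The cryptic transcript CUT377 rose by 3.45 ± 0.60 log2 units (edgeR adjusted p = 0.0250).

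Of 6191 features tested, 10 changed between 0 and 15 min, with 9 rises and 1 fall, and 423 had an unadjusted p under 0.05 where 310 were expected. Both libraries of one group lay above both of the other in all 10, a separation seen in 45.4% of all features and in 33.3% by chance. Passing the test nearly ensures this separation, so it adds no support of its own. The remaining rises were in ANB1, NCE103, ROX1, CIT2 and OLE1. ANB1, the form of the translation factor eIF5A made under low oxygen, rose by 3.15 ± 0.56 log2 units (edgeR adjusted p = 0.0310), from 19.7 ± 12.6 to 175 ± 13.0 CPM. NCE103, a carbonic anhydrase, rose by 1.62 ± 0.28, ROX1, a repressor of hypoxic genes, by 1.60 ± 0.26, and CIT2, the peroxisomal citrate synthase, by 1.51 ± 0.27 (edgeR adjusted p = 0.0250 for each). OLE1, the fatty acid desaturase, chosen after its values were seen, rose by 1.28 ± 0.24 (edgeR adjusted p = 0.0310). The fall was in RPS9A, a protein of the small ribosomal subunit and member of a paralog pair, at -1.55 ± 0.27 (edgeR adjusted p = 0.0250).

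Among feature groups at 15 min, 1 of 323 CUTs rose and none fell over all genes, and the same number passed adjusted over the list alone. The 323 are those of 925 CUTs that passed the count filter, which a CUT could do through the libraries after rapamycin alone. The CUT median was 1.18, with an interquartile range from 0.08 to 2.06 (camera adjusted p = 1.36e-06, and adjusted p = 0.7 with an estimated correlation). None of 27 snoRNAs passed over all genes or adjusted over the list alone, and their median was 0.80 (camera adjusted p = 0.000424, and adjusted p = 0.593 with an estimated correlation). Under scaling on snoRNA features the snoRNA median is -0.07 by construction. Of 8 structural noncoding RNAs none passed over all genes and 4 rose adjusted over the list alone, with a median of 0.89 (camera adjusted p = 0.000145, and adjusted p = 0.167 with an estimated correlation). Of 13 genes known for Nrd1-dependent early termination, NRD1 and HRP1 rose over all genes and 3 rose adjusted over the list alone. That list's median was 0.30 (camera adjusted p = 0.00697, and adjusted p = 0.308 with an estimated correlation), and it turned to -0.18 and -0.59 under scaling on mitochondrial genome features and on snoRNA features. Of 65 genes of the mitochondrial ribosome none passed over all genes and 1 fell adjusted over the list alone, with a median of -0.72 (camera adjusted p = 1.47e-05, and adjusted p = 0.149 with an estimated correlation). None of 10 histone genes passed over all genes and 5 fell adjusted over the list alone, with a median of -0.70 (camera adjusted p = 0.00026, and adjusted p = 0.593 with an estimated correlation). Of 34 proteasome genes 1 fell adjusted over the list alone and none passed over all genes, with a median of -0.33 (camera adjusted p = 0.0121, and adjusted p = 0.593 with an estimated correlation). The 138 genes of the cytoplasmic ribosome had 1 fall by either adjustment and a median of 0.18 (camera adjusted p = 0.00142, and adjusted p = 0.739 with an estimated correlation), which turned to -0.29 and -0.66 under scaling on mitochondrial genome and snoRNA features. Of the 24 genes of nuclear RNA decay, NRD1 and TRF5 rose, 2 rose and 2 fell adjusted over the list alone, and 17 had a negative fold change, with a median of -0.27 (camera adjusted p = 0.187). Of 44 genes of polyadenylation and mRNA export HRP1 alone rose by either adjustment, with a median of -0.14 (camera adjusted p = 0.992).

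The early count rests on few libraries: it was 0 without 15 min replicate 1 (180 features at an unadjusted p under 0.05), 20 without 15 min replicate 2, 52 without 0 min replicate 2, 38 without 30 min replicate 2, 22 without control replicate 1, 16 without control replicate 2, and 5, of which 1 was among the 10, without the 3 libraries of low complexity. By total library size 37.9% of 29 calls were rises, by snoRNA features 5.5% of 91 were, mitochondrial scaling left 0 calls (445 at an unadjusted p under 0.05), and the DESeq2 Wald test and limma-voom gave 67 and 61 calls with 59.7% and 63.9% rises, against 90% rises among the 10.

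The comparison of 30 min with 0 min addresses the later change in the same strain, where rapamycin exposure and time change together with anchoring. NRD1, HRP1 and TRF5 were higher than at 0 min, and RPL27B and TOM6 were lower. NRD1 reached 502 ± 25.2 CPM and HRP1 1237 ± 15.7 (mean ± SD, n = 2), with log2 fold changes of 2.01 ± 0.26 (SE, edgeR adjusted p = 0.000879) and 1.58 ± 0.24 (edgeR adjusted p = 0.00251). TRF5 rose by 2.20 ± 0.36 log2 units (edgeR adjusted p = 0.00411). RPL27B (feature ST0761, chromosome IV, 1401770 to 1402564), a gene of the large ribosomal subunit with a paralog, went from 1360 ± 156 to 342 ± 28.9 CPM, a log2 fold change of -1.99 ± 0.25 (edgeR adjusted p = 0.000634). TOM6 (feature ST3114, chromosome XV, 413852 to 414037), a small protein of the mitochondrial import pore, went from 43.0 ± 10.7 to 2.54 ± 3.32 CPM, a log2 fold change of -3.98 ± 0.86 (edgeR adjusted p = 0.0188).

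Of 6191 features, 171 changed between 0 and 30 min, with 31 rises and 140 falls, and 912 had an unadjusted p under 0.05. All 171 were separated between the groups, which passing the test nearly ensures, against 47.7% of all features and 33.3% by chance. Of the changes, 26 rises and 139 falls were ORF transcripts. The largest rises were SUT198 at 4.67 ± 0.78, SUT307 at 3.32 ± 0.68 and SUT445 at 3.12 ± 0.54, then GIP2, a regulator of a protein phosphatase, at 3.08 ± 0.74, and the composite feature YLR342W-A/GAS2 at 3.00 ± 0.71. CTA1, the peroxisomal catalase, rose by 2.89 ± 0.60, CUT377 by 2.86 ± 0.59 and NRG1, a repressor of glucose-repressed genes, by 2.61 ± 0.61. CUT557 rose by 2.47 ± 0.62. The edgeR adjusted p-values of these 9 lay between 0.00498 for SUT198 and 0.0384 for CUT557. After TOM6 the largest falls were in POP5, a subunit of RNases P and MRP, at -3.33 ± 0.62, MMS2, a ubiquitin-conjugating variant of DNA repair, at -2.95 ± 0.59, AAH1, adenine deaminase, at -2.93 ± 0.72, and LAC1, a ceramide synthase subunit, at -2.84 ± 0.62. RPL18B fell by 2.76 ± 0.34, RPB11, a subunit of RNA polymerase II, by 2.66 ± 0.52, and the composite RPL7B/SNR59 by 2.54 ± 0.34 log2 units. The edgeR adjusted p-values of these 7 falls lay between 0.000634 for RPL18B and 0.0382 for AAH1.

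Of 138 genes of the cytoplasmic ribosome 16 fell and none rose over all genes, and 26 fell adjusted over the list alone, with a median of -0.39 (camera adjusted p = 1.1e-06, and adjusted p = 0.551 with an estimated correlation). Examples are RPL11B at -1.34 ± 0.25 (edgeR adjusted p = 0.00783) and RPL4A at -1.12 ± 0.28 (edgeR adjusted p = 0.0402). Among the 101 with an intron feature 14 fell and among the 37 without one 2 fell, with medians of -0.39 and -0.38. Of 65 ribosome biogenesis genes 6 fell, 12 adjusted over the list alone, with a median of -0.60 (camera adjusted p = 9.76e-05, and adjusted p = 0.551 with an estimated correlation). They include NSR1, a nucleolar protein, at -1.45 ± 0.30, RRB1, a chaperone of a ribosomal protein, at -1.43 ± 0.27, and RPA135, a subunit of RNA polymerase I, at -1.02 ± 0.26 (edgeR adjusted p = 0.0382), a call lost in 17 of 22 alternatives. Of 65 mitochondrial ribosome genes 2 fell by either adjustment, RSM7 at -2.13 ± 0.42 and MRPS12 at -1.66 ± 0.44, with a median of -0.57 (camera adjusted p = 0.00356, and adjusted p = 0.282 with an estimated correlation). Of 34 proteasome genes 4 fell, and 2 rose and 7 fell adjusted over the list alone, among them the core subunits PUP3 at -1.94 ± 0.31 and PRE5 at -1.19 ± 0.28. Their median was 0.03 and their mean -0.20 (camera adjusted p = 0.795). Of 10 histone genes HTA2 fell by 1.12 ± 0.28 log2 units and 3 fell adjusted over the list alone (camera adjusted p = 0.27). None of 24 ergosterol genes passed over all genes and 2 fell adjusted over the list alone, with a median of -0.50 (camera adjusted p = 0.0344, and adjusted p = 0.551 with an estimated correlation).

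Of 29 features of 28 genes under nitrogen catabolite repression 3 rose and none fell, and 6 rose adjusted over the list alone. The list's median was 0.20 (camera adjusted p = 0.0125, and adjusted p = 0.488 with an estimated correlation). It turned to -0.24 and -0.44 under scaling on mitochondrial genome and snoRNA features. The rises include the transcription factor gene GAT1 (feature ST0993) at 1.62 ± 0.32 (edgeR adjusted p = 0.0108) and the ammonium permease gene MEP2 at 1.47 ± 0.31 (edgeR adjusted p = 0.0132). Of 26 chaperone genes HSP42, a small heat shock protein, rose by 1.84 ± 0.31 (edgeR adjusted p = 0.00442), and HSP10, the mitochondrial co-chaperonin, fell by 1.89 ± 0.29 log2 units (edgeR adjusted p = 0.00259). In that list 7 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0596). Of 39 amino acid genes under Gcn4, LYS1 rose by 1.21 ± 0.29 and ILV1 fell by 1.15 ± 0.26, and 2 rose and 4 fell adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.119). The haem oxygenase gene HMX1 rose by 1.29 ± 0.31 as the only 1 of 23 iron genes (camera adjusted p = 0.119), and VTC1, of the polyphosphate synthase complex, fell by 1.39 ± 0.29 as the only 1 of 13 phosphate genes (camera adjusted p = 0.564). ENO1, an enolase, fell by 0.94 ± 0.24 log2 units as the only 1 of 20 glycolysis genes, with a median of -0.29 for the list (camera adjusted p = 0.157). Of 24 genes of nuclear RNA decay NRD1 and TRF5 rose, 2 rose and 1 fell adjusted over the list alone, and 18 had a negative fold change, with a median of -0.27 (camera adjusted p = 0.504). Of 44 genes of polyadenylation and mRNA export HRP1 rose, with 1 rise and 1 fall adjusted over the list alone and a median of 0.03 (camera adjusted p = 0.326). Of 323 CUTs 2 rose and none fell, 1 adjusted over the list alone, with a median of 1.12 (camera adjusted p = 1.3e-05, and adjusted p = 0.551 with an estimated correlation). Of 507 SUTs 3 rose and none fell (camera adjusted p = 0.0732). None of 23 cyclin and other short-lived cell cycle transcripts passed by either adjustment, with a median of 0.64 (camera adjusted p = 0.000196, and adjusted p = 0.282 with an estimated correlation). The 8 structural noncoding RNAs had a median of 0.66 with 3 rises adjusted over the list alone (camera adjusted p = 0.00633, and adjusted p = 0.309 with an estimated correlation), and 6 tRNA features a median of 2.70 with none passing (camera adjusted p = 0.0193, and adjusted p = 0.429 with an estimated correlation). All tRNA features together had only 157 and 204 counts at 0 min and 238 and 201 at 30 min. The 6 genes specific to mating type a had a median of 1.68 with 1 rise adjusted over the list alone (camera adjusted p = 0.0124, and adjusted p = 0.429 with an estimated correlation). The 5 alpha-specific genes were all negative, with a median of -0.88, 1 fall over all genes, in MF(ALPHA)2, and 2 adjusted over the list alone (camera adjusted p = 0.0732). Of 64 intron features the HAC1 intron, removed in the unfolded protein response, fell by 1.35 ± 0.27 log2 units (edgeR adjusted p = 0.0121).

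Fitted to only the 4 libraries compared, edgeR called 0 features, with 850 at an unadjusted p under 0.05, while DESeq2 and limma-voom on all 8 called 311 with 36.3% rises and 347 with 25.9%, scaling on mitochondrial genome features 15 with 0% rises, on snoRNA features 326 with 1.2% rises, and on total library size 141 with 33.3% rises against 18.1%. The count was 40 without 0 min replicate 1, 442 without 30 min replicate 1, and 256, of which 110 were among the 171, without the 3 libraries of low complexity. Among named genes TOM6 did not pass in 8 of 22 alternatives, among them those without 0 min replicate 1, without either 15 min library and without control replicate 2, with log2 fold changes from -7.71 to -3.15 over all settings. AAH1, ENO1, HTA2, ILV1, MRPS12 and PRE5 did not pass in 12 to 15 of 22.

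**Figure D2:**
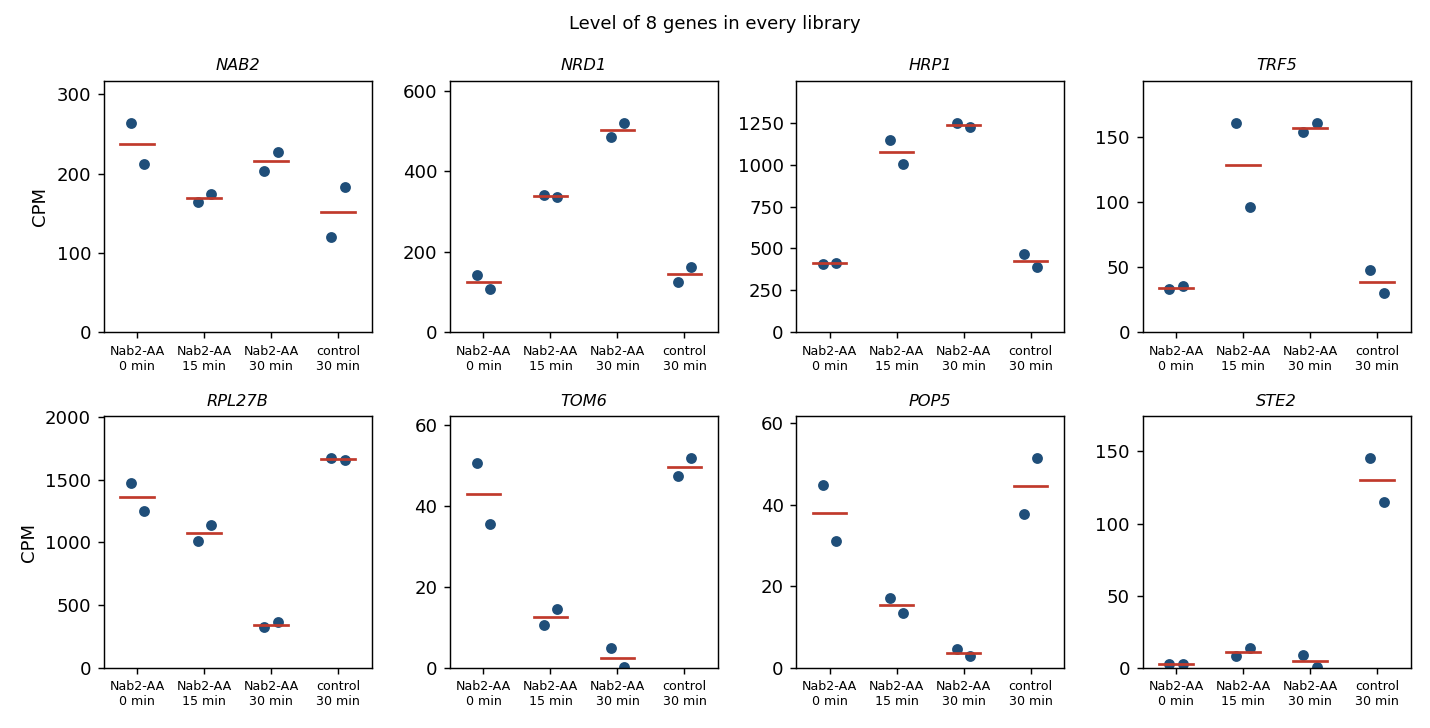
CPM of 8 genes in every library, by group; points are the 2 libraries of each group and red lines their mean. NRD1 and HRP1 are higher at 15 and 30 min than at 0 min and in the control, RPL27B has a mean of 342 at 30 min against 1666 in the control, and STE2 is highest in the control.

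The comparison of 30 min with the control addresses Nab2 anchoring at equal rapamycin exposure, with strain and anchoring changing together. NRD1, HRP1 and TRF5 were higher than in the control, and RPL27B, TOM6 and POP5 were lower. NRD1 had 502 ± 25.2 CPM against 144 ± 27.0 and HRP1 1237 ± 15.7 against 428 ± 56.6 (mean ± SD, n = 2). Their log2 fold changes were 1.80 ± 0.26 (SE, edgeR adjusted p = 0.000768) and 1.53 ± 0.24 (edgeR adjusted p = 0.00122), and that of TRF5 was 2.02 ± 0.36 (edgeR adjusted p = 0.00312). RPL27B fell by 2.28 ± 0.25 (edgeR adjusted p = 0.000142), TOM6 by 4.18 ± 0.86 (edgeR adjusted p = 0.00877) and POP5 by 3.56 ± 0.63 log2 units (edgeR adjusted p = 0.00281). Genes of mating type differed too. The anchor-away strain differed from the control in the same direction at 0 min, before rapamycin, so this difference does not need anchoring. STE3 (feature ST5646, chromosome XI, 113215 to 114627), the receptor of alpha cells, was higher in the anchor-away strain by 6.89 ± 0.90 (edgeR adjusted p = 0.000378). STE2 (feature ST0989, chromosome VI, 82580 to 83875), the receptor of a cells, was lower at -4.66 ± 0.79 (edgeR adjusted p = 0.00286).

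Of 6191 features, 376 differed, with 81 higher and 295 lower at 30 min than in the control, and 1288 had an unadjusted p under 0.05. All 376 were separated, which passing the test nearly ensures, against 47.1% of all features and 33.3% by chance. The alpha pheromone gene MF(ALPHA)2 had 381 counts at 30 min and 3 in the control. Relative to the scaled library totals the ratio was 133, with a 95% counting interval of 45.2 to 648 (edgeR adjusted p = 0.000142). The composite GAL7/GAL10 had 299 counts and 3, a scaled ratio of 104 with an interval of 35.4 to 509 (edgeR adjusted p = 0.0384). Apart from these 2 and STE3 the largest rises were CUT866 at 6.37 ± 1.80, SUT198 at 6.05 ± 0.86, PYP1 at 5.84 ± 1.49, YER053C-A at 5.67 ± 1.19 and BTN2, a factor that sorts misfolded protein, at 5.39 ± 0.86. Their edgeR adjusted p-values lay between 0.000768 for SUT198 and 0.0422 for CUT866. Apart from STE2, TOM6 and POP5 the largest falls were AGA2, the a-agglutinin binding subunit, at -5.22 ± 1.29, SUT721 at -4.67 ± 1.25, PFA4, a palmitoyltransferase, at -3.62 ± 0.94, SUT645 at -3.51 ± 0.76, and COA6, a cytochrome oxidase assembly factor, at -3.21 ± 0.81. Their edgeR adjusted p-values lay between 0.00993 for SUT645 and 0.032 for SUT721.

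Of the 5 alpha-specific genes 4 were higher than in the control over all genes and 5 adjusted over the list alone, among them the barrier protein AFB1 at 2.83 ± 0.27 (edgeR adjusted p = 3.72e-05; camera adjusted p = 4.99e-07, and adjusted p = 0.265 with an estimated correlation). Of the 6 a-specific genes STE2 and AGA2 were lower, 3 adjusted over the list alone, with a median of -2.36 (camera adjusted p = 0.00154, and adjusted p = 0.306 with an estimated correlation). Of 6 pheromone response genes AGA1 alone passed, at 3.46 ± 0.66 (camera adjusted p = 0.0899). Of 138 ribosomal protein genes 23 fell and none rose, 47 adjusted over the list alone, with a median of -0.61 (camera adjusted p = 1.95e-10, and adjusted p = 0.49 with an estimated correlation). RPL18B fell by 2.99 ± 0.35, RPL4B by 1.39 ± 0.29 and RPL11B by 1.29 ± 0.25. Whether the falls of ribosomal protein genes follow a trend with abundance was not tested in this comparison. Of 65 ribosome biogenesis genes 10 fell, 12 adjusted over the list alone, among them NHP2 at -1.44 ± 0.29, with a median of -0.36 (camera adjusted p = 0.0157, and adjusted p = 0.744 with an estimated correlation). Of 65 mitochondrial ribosome genes 4 fell, 6 adjusted over the list alone, among them RSM7 at -2.51 ± 0.42 and RSM19 at -2.09 ± 0.49, with a median of -0.47 (camera adjusted p = 0.0103, and adjusted p = 0.306 with an estimated correlation). Of 34 proteasome genes 5 fell, among them PUP3 at -2.15 ± 0.31 and PUP1 at -1.43 ± 0.27, and 1 rose, with 1 rise and 8 falls adjusted over the list alone (camera adjusted p = 0.528). Of 10 histone genes 3 fell by either adjustment, among them HTZ1, the variant H2A.Z, at -2.33 ± 0.49 and HHO1, the linker histone, at -1.67 ± 0.33 (camera adjusted p = 0.227).

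Of 26 chaperone genes 3 rose and 3 fell over all genes, and 7 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.285), with HSP42 at 2.09 ± 0.32 and HSP10 at -1.99 ± 0.30. Of 23 cell cycle transcripts MCD1, a cohesin subunit, rose by 2.52 ± 0.48 and CLB5, an S-phase cyclin, by 2.31 ± 0.64, and 6 rose adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.0103, and adjusted p = 0.381 with an estimated correlation). Of 24 ergosterol genes 1 rose and 3 fell, and 1 rose and 5 fell adjusted over the list alone, with a median of -0.45 (camera adjusted p = 0.0228, and adjusted p = 0.49 with an estimated correlation). The rise was ERG5 at 2.38 ± 0.52, and NCP1 fell by 1.18 ± 0.26. Of 24 genes of nuclear RNA decay NRD1 and TRF5 rose, 2 rose and 1 fell adjusted over the list alone, and 13 had a negative fold change, with a median of -0.11 and a mean of 0.21 (camera adjusted p = 0.918). Of 44 genes of polyadenylation and mRNA export, HRP1 and the cleavage factor gene RNA14 rose, RNA14 by 4.78 ± 1.19, and the export adaptor gene YRA2 fell by 1.92 ± 0.55, with 3 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.294). Of 29 features of nitrogen genes GAT1 (feature ST0993) rose by 1.46 ± 0.32 and PUT1, proline oxidase, by 1.18 ± 0.34. Of 13 phosphate genes PHO81, a kinase inhibitor, rose by 2.94 ± 0.78 and VTC1 fell by 1.58 ± 0.30. Of 37 respiratory chain genes COX9 fell by 1.43 ± 0.37 and ATP17 by 1.79 ± 0.47, the same number by either adjustment (camera adjusted p = 0.84). None of 30 features of stress genes under Msn2 and Msn4 passed by either adjustment (camera adjusted p = 0.3).

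Of 323 CUTs 3 rose and none fell, 2 adjusted over the list alone, with a median of 1.62 and an interquartile range from 0.48 to 3.03 (camera adjusted p = 5.95e-07, and adjusted p = 0.716 with an estimated correlation). ORF transcripts matched to the CUTs on mean abundance had a median of 1.64 in this comparison, 0.33 for 30 over 0 min and -0.48 for 15 over 0 min. Of 507 SUTs 4 rose and 2 fell, and 2 rose and 1 fell adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.024, and adjusted p = 0.747 with an estimated correlation). Among 27 snoRNAs SNR86 rose by 1.97 ± 0.44 (edgeR adjusted p = 0.0200; camera adjusted p = 0.428 for the list), and among 3 tested snRNA features the composite SNR7-L/SNR7-S, the U5 RNA, rose by 1.93 ± 0.42 (edgeR adjusted p = 0.0102). The 6 tRNA features had a median of 3.68 with none passing (camera adjusted p = 0.0341, and adjusted p = 0.448 with an estimated correlation). That median rests on few counts, because all tRNA features together had 238 and 201 at 30 min and 50 and 106 in the control. The fry test, which asks whether a list moves on balance in one direction, passed for 7 of 31 lists, ribosomal proteins among them (fry adjusted p = 0.0452).

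The split of rises and falls depends on scaling: 21.5% of the 376 were rises, against 52.4% of 313 by total library size, 32.7% of 297 by upper-quartile scaling and 6.6% of 106 on mitochondrial genome features, and DESeq2 called 700 with 40.7% rises. The count was 243 without control replicate 1, 603 without 30 min replicate 1, and 295, of which 179 were among the 376, without the 3 libraries of low complexity. PYP1, ERG5 and YRA2 did not pass in 11, 12 and 14 of 21 alternatives. COX9 and ATP17 did not pass in 10 each, CUT866 and COA6 in 9 each, and CLB5 in 8. The log2 fold change of GAL7/GAL10 ran from 5.38 to 10.73 over these settings.

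Both 30 min comparisons share the 30 min libraries. Between them 21 features rose in both, where 0.406 would by chance, and 136 fell in both, where 6.671 would. In simulated draws with the same shared libraries and no change, 0.05 rose in both on average and 0.05 fell in both. The draws hold no changed features. Here and below they therefore cannot tell how much of the overlap of called features comes from the shared libraries. The log2 fold changes had a covariance of 1.466 across features, against 0.884 in the draws, and features are not independent replicates. Only MF(ALPHA)2 passed in opposite directions, at -2.28 ± 0.54 against 0 min and higher than the control as given above. Between 15 and 30 min over 0 min, which share the 0 min libraries, 5 features rose in both and 1 fell in both, against 0.175 and 0.15 in the draws, and the covariance was 0.631 against 0.814.

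The comparison of 30 with 15 min tests whether the change from 0 min differed between the times. RPL27B, RPL18B and RPB11 fell between the times. RPL27B went from 1075 ± 88.0 to 342 ± 28.9 CPM (mean ± SD, n = 2), a log2 fold change of -1.65 ± 0.25 (SE, edgeR adjusted p = 0.0187), and RPL18B fell by 2.00 ± 0.34 (edgeR adjusted p = 0.0206). RPB11 fell by 2.61 ± 0.52 (edgeR adjusted p = 0.0358) and the composite RPL7B/SNR59 by 2.01 ± 0.34 log2 units (edgeR adjusted p = 0.0206). HSP42 rose by 1.45 ± 0.31 and RNR1, a subunit of ribonucleotide reductase, by 1.11 ± 0.24 (edgeR adjusted p = 0.0474 for each).

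Of 6191 features 28 changed between 15 and 30 min, with 2 rises and 26 falls, and 658 had an unadjusted p under 0.05. All 28 were separated, which passing the test nearly ensures, against 40.9% of all features and 33.3% by chance. Of 138 ribosomal protein genes 9 fell and none rose over all genes, and 49 fell adjusted over the list alone, with a median of -0.60 (camera adjusted p = 4.46e-17, and adjusted p = 0.586 with an estimated correlation). The medians were -0.63 for those with an intron feature and -0.58 for those without. Other genes matched on mean abundance had a median of -0.47. Of 65 ribosome biogenesis genes RRB1 fell by 1.35 ± 0.27 (edgeR adjusted p = 0.0371) and 7 fell adjusted over the list alone, with a median of -0.44 (camera adjusted p = 0.000504, and adjusted p = 0.628 with an estimated correlation). None of 24 ergosterol genes passed over all genes and 6 fell adjusted over the list alone, with a median of -0.51 (camera adjusted p = 5.18e-05, and adjusted p = 0.586 with an estimated correlation). Glycolysis genes had a median of -0.47 over 20 members (camera adjusted p = 0.0346, and adjusted p = 0.688 with an estimated correlation) and genes under Gcn4 -0.41 over 39 (camera adjusted p = 0.0092, and adjusted p = 0.628 with an estimated correlation), each with 1 fall adjusted over the list alone. Among 23 cell cycle transcripts RNR1 rose and 4 rose adjusted over the list alone, with a median of 0.43 (camera adjusted p = 0.0157, and adjusted p = 0.586 with an estimated correlation). NRD1 had a log2 fold change of 0.57 ± 0.25 between the times (edgeR adjusted p = 0.426), HRP1 0.20 ± 0.24 (edgeR adjusted p = 0.853) and TRF5 0.29 ± 0.35 (edgeR adjusted p = 0.859), so no difference between the times was detectable for them.

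This count changed with the libraries used: it was 0 without 15 min replicate 1, without 30 min replicate 2 and without all 3 libraries of low complexity (264, 557 and 427 at an unadjusted p under 0.05), 4 without 15 min replicate 2, 19 without control replicate 2, 282 without 30 min replicate 1, 98 without 0 min replicate 2, 70 without 0 min replicate 1 and 49 without control replicate 1. It was also 0 on mitochondrial genome features (161 at an unadjusted p under 0.05) and with a group mean of at least 50 counts (616), 1 on snoRNA features, 5 (3 rises and 2 falls) by total library size, and 157 and 76 with the DESeq2 Wald test and limma-voom. RPB11 did not pass in 14 of 21 alternatives and RRB1 in 11.

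**Figure D3:**
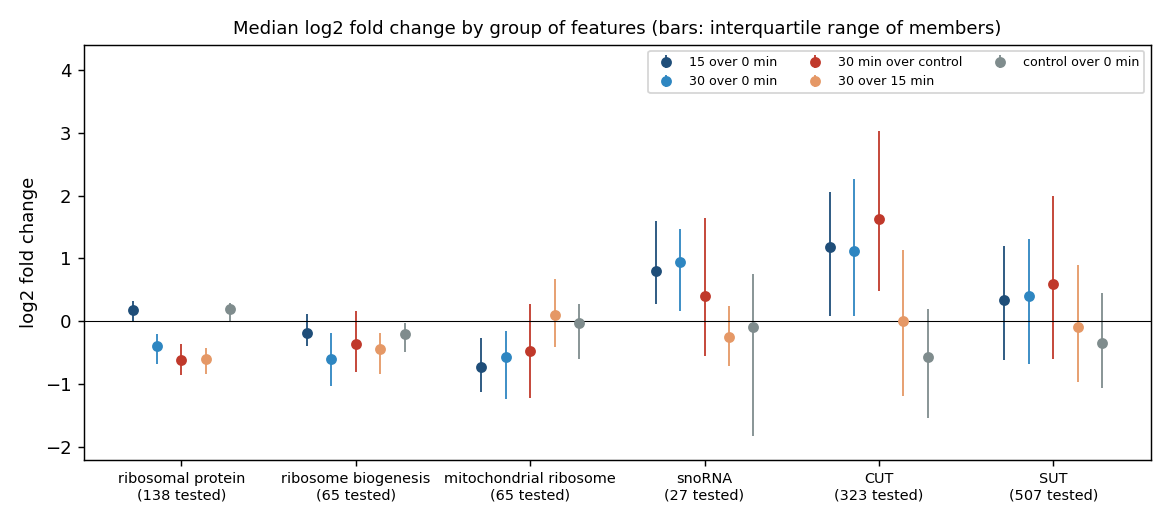
Median log2 fold change of 6 groups of features in the 5 comparisons; points are medians over the tested members and bars span their interquartile range. The CUT median is 1.18, 1.12 and 1.62 in the 3 comparisons with an anchor-away group after rapamycin and -0.57 for control over 0 min, and the ribosomal protein median is 0.18 at 15 min, where it turns negative under scaling on mitochondrial genome or snoRNA features, and -0.39 at 30 min.

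The control at 30 min against the anchor-away strain at 0 min gives the background of strain and rapamycin without anchoring. It held 5 changes, with 1 rise and 4 falls, and 110 features at an unadjusted p under 0.05 where 310 were expected. With fewer than expected, the test may be too strict for this comparison. The low number of calls therefore does not show that the background is small. All 5 were mating genes. STE2 was higher in the control by 5.61 ± 0.82 log2 units (SE, edgeR adjusted p = 0.00701), at 145 and 115 CPM against 2.66 and 2.65. STE3 was lower at -7.88 ± 0.92 (edgeR adjusted p = 0.000243), AFB1 at -3.72 ± 0.28 (edgeR adjusted p = 9.19e-07) and SAG1, the alpha-agglutinin, at -2.14 ± 0.28 (edgeR adjusted p = 0.000685). MF(ALPHA)2 had 3179 counts at 0 min and 3 in the control. Relative to the scaled library totals the ratio was 577, with a 95% counting interval of 197 to 2800 (edgeR adjusted p = 7.26e-06). Of 6 a-specific genes 6 were higher in the control adjusted over the list alone (camera adjusted p = 2.59e-19, and adjusted p = 0.0161 with an estimated correlation), and of 5 alpha-specific genes 5 were lower adjusted over the list alone (camera adjusted p = 3.6e-21, and adjusted p = 0.0161 with an estimated correlation). All 5 changes were separated, which passing the test nearly ensures, against 32.4% of all features.

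Ribosomal protein genes had a median of 0.20 in this background comparison with none passing by either adjustment (camera adjusted p = 1.07e-05, and adjusted p = 0.752 with an estimated correlation), which turned to -0.18 under scaling on snoRNA features. CUTs had a median of -0.57 with none passing (camera adjusted p = 0.016, and adjusted p = 0.752 with an estimated correlation), which turned to 0.05 without the 3 libraries of low complexity. Nitrogen genes had a median of 0.16 with none passing (camera adjusted p = 0.00579, and adjusted p = 0.639 with an estimated correlation), which turned to -0.02 by total library size and -0.11 on snoRNA features. The 6 pheromone response genes had a median of -0.79 with none passing (camera adjusted p = 0.00579, and adjusted p = 0.749 with an estimated correlation). NRD1 had a log2 fold change of 0.20 ± 0.25, HRP1 of 0.05 ± 0.24 and TRF5 of 0.18 ± 0.35, none of which passed. The count was 30 without 0 min replicate 1, 17 without control replicate 2 and 9 without the 3 libraries of low complexity, with 14 calls by DESeq2, 3 on mitochondrial genome features (0 rises), 23 on snoRNA features and 10 in a fit to only the 4 libraries compared.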

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

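Of the tests below, those on low counts within single comparisons, on libraries of low complexity, on scaling by snoRNA features, on a mislabelled library and on rapamycin without anchoring were chosen only after the result was seen.

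For 28 features the change from 0 min differed between 30 and 15 min, by edgeR's test of the difference itself. Among them, with 30 min minus 15 min on the log2 scale, were RPB11 (-2.61), the composite RPL7B/SNR59 (-2.01), RPL18B (-2.00), REX2, an RNA exonuclease gene (-1.78), RPL27B (-1.65), INA1 (-1.64), GPI16, of the enzyme that attaches GPI anchors (-1.56), RPL43B (-1.54) and RPL31B (-1.50). Smaller differences included the HAC1 intron (-1.46), RPL11B (-1.39) and RRB1 (-1.35), and positive ones in HSP42 (1.45) and RNR1 (1.11). RPB11, REX2, GPI16 and RRB1 did not pass in 14, 14, 12 and 11 of 21 alternatives. In a fit without the 3 libraries of low complexity 0 features passed this test.

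Between 15 and 30 min 9 of 138 ribosomal protein genes fell, and the list had a median of -0.60, with an interquartile range from -0.83 to -0.42. A trend with coding length is argued against: 131 of the genes have a known coding length, at a median of 432 bases against 1311 for other ORF transcripts, and genes matched on coding length had a median of -0.11. Libraries of low complexity cannot be told apart as a source: without them the list lay at -0.92 relative to all ORF transcripts, but that sets 1 library at 15 min against 1 at 30 min. A trend with abundance stays open and could account for much of the fall, because other genes matched on mean abundance had a median of -0.47. Longer anchoring of Nab2, longer rapamycin exposure and time, which change together between 15 and 30 min, also stay open and were not tested apart from it.

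CUT medians were 1.18, 1.12 and 1.62 for 15 over 0 min, 30 over 0 min and 30 min over the control, where 1, 2 and 3 of 323 CUTs rose (camera adjusted p = 0.7, 0.551 and 0.716 with an estimated correlation), and the test of shares did not pass (exact test adjusted p = 0.0572). Libraries of low complexity cannot be told apart for the medians. Without them the ratio of CUT shares was 2.73 over 2 libraries against 3. All anchor-away libraries after rapamycin already lay above the others, which fixed the direction of that ratio. It shows only that the CUT share was also higher among libraries of ordinary complexity. The CUT median for control over 0 min went from -0.57 to 0.045 without the libraries of low complexity. Low counts as such are argued against for 15 over 0 min by ORF transcripts matched on abundance, with a median of -0.48. The matching was not designed to address the count filter, which 323 of 925 CUTs and 5242 of 5425 ORF transcripts passed. A CUT could pass it through its level after rapamycin alone, which would raise the CUT medians. Low counts could account for the median of 30 min over the control, where the matched ORF transcripts reached 1.64, and cannot be told apart for 30 over 0 min (matched median 0.33), so over all 3 comparisons (highest matched median 1.64) that explanation stays open. A loss of other RNA under a scaling set by the bulk cannot be told apart from a rise of CUTs, since on snoRNA features the lowest CUT median was 0.32 and no spike-in counts were used. Nab2 loss stays open beside these.

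The 140 features that fell between 0 and 30 min had a median of -1.46, and might reflect libraries of low complexity, a mislabelled library, or rapamycin and time without anchoring. The last is argued against by the control strain, which carries the same rapamycin resistance and anchor per the labels. There these features had a median of 0.20 against 0 min (interquartile range 0.03 to 0.31). The 0 min libraries were also used to pick these features. The control libraries were not in the comparison that picked them, but entered the filter, scaling and dispersion of the shared fit. A swap of libraries between the strains is argued against by STE2, whose lowest control level of 114.6 CPM was 8.56 times its highest anchor-away level of 13.4, and by STE3, at least 26.9 CPM in anchor-away libraries and at most 0.448 in control libraries, although a mix-up among times or an admixture of some control RNA is not addressed. Low complexity cannot be told apart: without the 3 libraries 100.0% of the 140 had a negative log2 fold change, but all 140 were already separated between the groups, which fixed that sign, and the 88 that still passed rest on 1 library at 30 min. Nab2 loss stays open beside it, as does a strain difference in the response to rapamycin, which was not tested.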

How the results depend on the processing

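Library quality weights, the fits without the 3 libraries of low complexity (15 min replicate 1, 30 min replicate 2 and control replicate 1), the crossed replicate block and the comparison of class shares were chosen only after the results were seen. Counts of changed features are given in the order 15 over 0 min (10 with TMM), 30 over 0 min (171), 30 min over control (376), 30 over 15 min (28) and control over 0 min (5), wherever a setting moved them by more than 1.5 times or ended all calls. The cause was not tested, except that smaller fits have fewer samples.

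Scaling on mitochondrial genome features gave 0, 15, 106, 0 and 3. Scaling on snoRNA features gave 91, 326, 250, 1 and 23. Total library size gave 29 for 15 over 0 min and 5 for 30 over 15 min, and DESeq2 size factors 8 for 30 over 15 min. The DESeq2 Wald test gave 67, 311, 700, 157 and 14, and limma-voom 61, 347 and 76 for 15 over 0, 30 over 0 and 30 over 15 min. No filter on low counts gave 75 (49.3% rises), 318 (28.9%), 643 (37%), 133 (22.6%) and 40 (12.5%), and a group mean of at least 50 counts 111 for 30 over 0 min and 0 for 30 over 15 min. A fit to only the 4 libraries compared gave 0 for 30 over 0 min and 10 for control over 0 min. Quality weights gave 219 (45.7% rises), 272 (32%), 64 (12.5%) and 9 (44.4%) for 15 over 0, 30 over 0, 30 over 15 min and control over 0 min, and leaving out the 3 libraries of low complexity 5, 0 and 9 for 15 over 0, 30 over 15 min and control over 0 min. 

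With a replicate block the counts were 17, 179, 396, 37 and 7. The pairing rests on the number 2 in the description of a 30 min library whose title gives 3, so block counts depend on that choice. Same-numbered replicates deviated with correlations from -0.263 to 0.11 across features, and a crossed replicate block gave 134 for 30 over 0 min and 20 for control over 0 min. Leaving out 1 library in turn, which leaves its group with a lone library assumed to vary like the others, gave 0 to 52, 40 to 442, 243 to 603, 0 to 282 and 5 to 30. The extremes were, in order, without 15 min replicate 1 and 0 min replicate 2, without 0 min replicate 1 and 30 min replicate 1, without control replicate 1 and 30 min replicate 1, without 15 min replicate 1 or 30 min replicate 2 and 30 min replicate 1, and, for the highest count of control over 0 min, without 0 min replicate 1.

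Camera called 10, 12, 12, 8 and 8 of 31 lists with the preset correlation, 0, 0, 0, 0 and 2 with an estimated correlation, and fry 0, 0, 7, 0 and 2. The ratio of shares over the libraries left out in turn was 2.53 to 3.02 for CUTs, 1.4 to 1.61 for SUTs, 1.59 to 1.7 for snoRNAs, 1.63 to 1.94 for snRNAs and 0.97 to 0.97 for ORF transcripts. Without the 3 libraries of low complexity it was 2.73, 1.6, 1.7, 1.74 and 0.97, with an exact p of 0.1, the smallest possible there.

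Lists that camera did not call with the preset correlation were not followed in this way. Among them, the SUT median for 15 over 0 min went from 0.34 to -0.12 on mitochondrial genome and -0.52 on snoRNA features. For 30 over 0 min it went from 0.41 to -0.37 on snoRNA features and to 0.18 on mitochondrial genome features. Medians of the lists that were called changed sign as follows. For 15 over 0 min on mitochondrial genome features, ribosomal proteins went to -0.287 (-0.292 with and -0.269 without an intron feature) and genes of Nrd1-dependent termination to -0.176. On snoRNA features these were -0.659, -0.664, -0.632 and -0.594, and snoRNAs went to -0.068. Nitrogen genes for 30 over 0 min went to -0.244 on mitochondrial genome and -0.44 on snoRNA features. For control over 0 min, ribosomal proteins went to -0.176 on snoRNA features (-0.19 with and -0.171 without an intron feature), nitrogen genes to -0.021 by total library size and -0.11 on snoRNA features, and CUTs to 0.045 without the 3 libraries of low complexity.

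Every feature that passed was separated between its groups, which nearly fixes its direction in fits that leave libraries out. Those fits therefore add no support on direction. Among 128 results of named features that passed, none changed direction in the settings run. Of these, 128 also passed with the DESeq2 Wald test, 123 with the replicate block, 115 with limma-voom, 112 with DESeq2 size factors, 73 on snoRNA features, 27 on mitochondrial genome features, 74 in a fit to only the 4 libraries compared and 68 without the 3 libraries of low complexity. Features at 0 did not follow total counts alone: control replicate 1, with 8883059 counts, had 28.2% of features at 0, and 15 min replicate 2, with 7562689, had 12.9%.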

Other observations

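The values in this part were chosen only after the results were seen, and no explanation was tested for them.

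ANB1, OLE1, ROX1, CIT2 and NCE103, which rose by 15 min, were followed to 30 min. They were picked for high values in the 15 min libraries, which also enter the comparison with 30 min, so some fall follows from the choice. ANB1 had 175 ± 13.0 CPM at 15 min and 33.4 ± 12.2 at 30 min (mean ± SD, n = 2), a log2 fold change of -2.38 ± 0.55 (SE) that did not pass (edgeR adjusted p = 0.0709). OLE1, which was higher at 15 min, went from 1864 to 775.7 CPM and fell by 1.26 ± 0.24 log2 units (edgeR adjusted p = 0.0317), and at 30 min its log2 fold change from 0 min was 0.02 ± 0.23. ROX1 had -0.74 ± 0.26 (edgeR adjusted p = 0.243), CIT2 -0.67 ± 0.26 (edgeR adjusted p = 0.319) and NCE103 -0.56 ± 0.27 (edgeR adjusted p = 0.484) between 15 and 30 min. NCE103 still passed at 30 min over 0 min, at 1.05 ± 0.28 (edgeR adjusted p = 0.0480). HEM13, a haem synthesis gene that Rox1 represses, had -0.02 ± 0.38 at 15 min.

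Across features, the log2 CPM of 0 min replicate 1 correlated with those of control replicate 2 at 0.985 and with those of 0 min replicate 2 at 0.946. Features are not independent replicates. The first 3 principal components held 30.4%, 29.6% and 19.1% of the variance between libraries.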
